A study of Mus musculus with 9 samples.

How the data were processed

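Thyroids of mice of 3 genotypes were profiled on 9 expression arrays, 3 per genotype: homozygous for ThrbPV, a dominant-negative mutant of thyroid hormone receptor beta, carrying KrasG12D, an activated form of the RAS protein Kras, or carrying both. The series describes its replicates as biological. Per the labels' protocols, total RNA was isolated with TRIzol and labelled with biotin, so that each array measured 1 sample in 1 colour. Wild-type thyroid was not analysed here, so no effect of either mutation alone against wild type, and no interaction of the 2 mutations, can be estimated.

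The deposited table held log2 values for 25700 probe sets on each of the 9 arrays, with no missing array, and no per-sample column was left unused. The submitters' processing notes name GCOS and limma without a version or a role. Background correction, summarisation and normalization are not given in the sources used here. That the values were log2 was taken from their range, 3.01 to 13.41 over the 9 arrays. Array medians lay between 6.22 and 6.31, so the arrays were taken as already on one scale and were not normalized again. On 42.2% of the probe sets (10838) at least 2 arrays held the identical value, to the decimals given. No detection calls, scan dates or control probe sets were among the values analysed here, so batches and the 3' to 5' ratio of RNA quality could not be examined, and the number of arrays is what limits the precision.

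Probe sets were named through the platform annotation: 20781 had 1 gene symbol, 235 had several and 4684 were unnamed here. Of the probe sets with 1 symbol, 20700 matched a gene of the current RefSeq gene table, and 0 symbols needed updating. Only probe sets with 1 symbol were used, which named 19664 genes. A probe set had to lie above its array's 40th percentile on at least 3 of the 9 arrays, whichever arrays these were. The probe set with the highest mean over all arrays stood for its gene, a choice that concerned 346 genes. This left 13178 genes. Where every array of the dimmer group lay under that percentile, the value there was treated as a bound, and the difference is given as "at least" a fold, the brighter group's mean against the mean filter level of the dimmer group's arrays.

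Group means were fitted over all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes, with no covariate), so that the 3 groups shared 1 estimate of the spread. Each pair of groups was compared, and a moderated F test asked whether any group differed. P-values were adjusted by the Benjamini-Hochberg method over the 13178 genes of a comparison, and an adjusted p under 0.05 counts as passing. Differences are log2, the first group named minus the second, and standard errors are limma's. Values in parentheses after a mean are SDs over the 3 arrays of a group.

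Before the data were examined, 15 gene lists of cell programs and 19 lists of markers of other cell types, sex and handling were fixed, along with the rule for named genes. The rule took, per comparison, the 8 largest rises and 8 largest falls among genes that passed and whose groups did not overlap, up to 4 measured members of each list with the smallest p, and always Thrb, Kras, Myc, Tg, Tpo, Slc5a5, Tshr, Pax8, Nkx2-1 and Foxe1. For the overlap of the double mutant's differences from both other groups it took the 6 rises and 6 falls with the largest smaller difference. Kras and Tpo had no probe set with 1 symbol here and were not analysed here. Lists with at least 3 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of one kind in a comparison, with camera at an estimated correlation and limma's fry as further tests. Of 87 such list tests, 34 were called at the preset correlation and all 34 calls were lost with an estimated correlation. By fry, which does not set a list against the other genes, only MAPK output kept its call in the double mutants against ThrbPV/PV (adjusted p = 0.00425). Against KrasG12D, fry kept every call but that of the unfolded protein response in ThrbPV/PV (adjusted p = 0.0854). Where fry is not named, a list call is camera's at the preset correlation. In 13 of the 87, none of them called, the list's median, mean and camera direction differed in sign: MYC targets, glycolysis and hypoxia, cartilage and peripheral nerve in the double mutant against ThrbPV/PV, Wnt targets, cartilage, airway epithelium, squamous epithelium and endothelial in the double mutant against KrasG12D, and Wnt targets, cartilage, airway epithelium and fibroblast in ThrbPV/PV against KrasG12D. The parathyroid, B cell, neutrophil, mast cell and erythroid lists had under 3 tested members and are given by gene.

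The fit was tested on simulated values for the same 13178 genes with 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale. For the double mutant against ThrbPV/PV it recovered 55.2%, 83.6% and 95.5% of them, and 4.88% of its calls were unchanged genes. The matching shares were 44.8%, 77.6%, 98.5% and 6.37% for the double mutant against KrasG12D, and 35.8%, 82.1%, 93.9% and 4.73% for ThrbPV/PV against KrasG12D. The list test called 20 of 20 shifted lists and 0 of 20 unshifted ones in the first of these comparisons. The simulated genes were drawn independently, whereas the estimated correlation within the real lists reached 0.844 (skeletal muscle). False calls from correlated members could therefore not appear in this simulation, and it does not speak for the preset correlation.

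The alternatives were quantile normalization, median centring, a floor at the 40th percentile, no filter, a filter at the median, the mean of a gene's probe sets, eBayes with a trend or with a trend and robust, array weights, a fit of only the groups compared, the replicate number as a block, a 2-fold threshold, and leaving out each array in turn. Chosen after the data had been seen were the mean level of the skeletal muscle or of the adipocyte markers as a covariate, the MAPK output list without immediate early genes, and leaving out genes with identical values on several arrays. Differences between lists were given 95% intervals from 10000 bootstrap draws of genes, and, for the list means on each array, t intervals from the spread of arrays within groups with 6 degrees of freedom, or 5 with a covariate. A difference was held to lie above 0 only if both intervals did. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.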

Results

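Total RNA from thyroids of 3 genotypes was measured on 9 arrays, 3 each for ThrbPV/PV mice, KrasG12D mice and mice with both mutations, called double mutants here. All values are log2 signals. The array medians ranged from 6.22 to 6.31, and arrays of a genotype correlated with each other at r = 0.989 to 0.995 over all probe sets. Double mutant and ThrbPV/PV arrays correlated at 0.981 to 0.990, and KrasG12D arrays with the others at 0.960 to 0.972. The first principal component, 60.7% of the variance, set the KrasG12D arrays apart from the other 6, and the next, 15.2%, parted the double mutants from ThrbPV/PV. Over the 3 groups 4577 of 13178 genes differed by limma's F test. Leaving out 1 array at a time, the lowest count was 2975, without KrasG12D replicate 1.

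Thrb, one of the mutated genes, lay at 6.03 (SD 0.19) in the double mutants, 6.46 (0.33) in ThrbPV/PV and 6.62 (0.16) in KrasG12D. A probe set reads the amount of transcript and not the mutation, so these levels do not check the genotypes, and Kras was not analysed here. Thyroglobulin (Tg), the hormone precursor of the follicular cell, was at the top of the scale in every group, at 13.21, 13.30 and 13.36, and the thyroid transcription factor Pax8 lay at 11.70, 11.83 and 11.85. Neither passed the test in any comparison, but Tg was the highest value on each of the 9 arrays, so a difference in it could not have been read. The Y-linked genes Kdm5d (8.03 to 8.31) and Uty (8.44 to 8.93) were detected on all 9 arrays, with Xist at 4.16 to 4.38.

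The double mutants were compared with ThrbPV/PV to ask what activated Kras adds to a thyroid that already carries the mutant receptor. Transcripts of surfactant protein B (Sftpb), granzyme E (Gzme), arginase 1 (Arg1) and mucin 1 (Muc1) rose, together with 10 of 24 genes that the MAPK pathway switches on and with collagen VI. The type 1 deiodinase Dio1, which activates thyroid hormone, fell by 2.57, from 11.26 (SD 0.36) to 8.69 (0.44). A few genes of oxidative phosphorylation (4 of 26), of the interferon response (1 of 15) and of the unfolded protein response (2 of 19) fell, and the calls of these lists were lost with an estimated correlation. In all, 612 genes passed, 268 higher and 344 lower, and 60 and 70 of them differed by at least 2-fold. In 30.1% of all tested genes the groups did not overlap, against 10% by chance.

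Sftpb had the largest rise, 3.95 (SE 0.57, adjusted p = 0.0149), from 7.53 (SD 0.96) to 11.48 (0.33). Gzme rose at least 4.58-fold (adjusted p = 4.08e-06), from 4.35, under the filter level on each ThrbPV/PV array, to 7.76. Arg1 rose at least 6.03-fold (5.09 to 8.16) and the intestinal-type keratin Krt20 at least 2.68-fold (4.55 to 6.99). The rises of the G protein subunit Gng4, of Clca3b, of the noncoding RNA Meg3 and of Muc1 were 3.26, 3.12, 2.93 and 2.53. Beside Dio1, the larger falls included the amino acid transporter Slc38a3 (-2.18), the carboxypeptidase N subunit Cpn1 (-2.07), and the macrophage genes Ms4a7 (-1.88) and Cd180 (-1.85). Cd5l, a protein secreted by macrophages, was at least 2.03-fold lower (4.63 against 6.62). The falls of the cartilage gene Cnmd (-2.89, adjusted p = 0.0485) and of the peptide hormone Adm2 (-2.30, adjusted p = 0.0453) were close to the threshold.

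**Figure D1:**
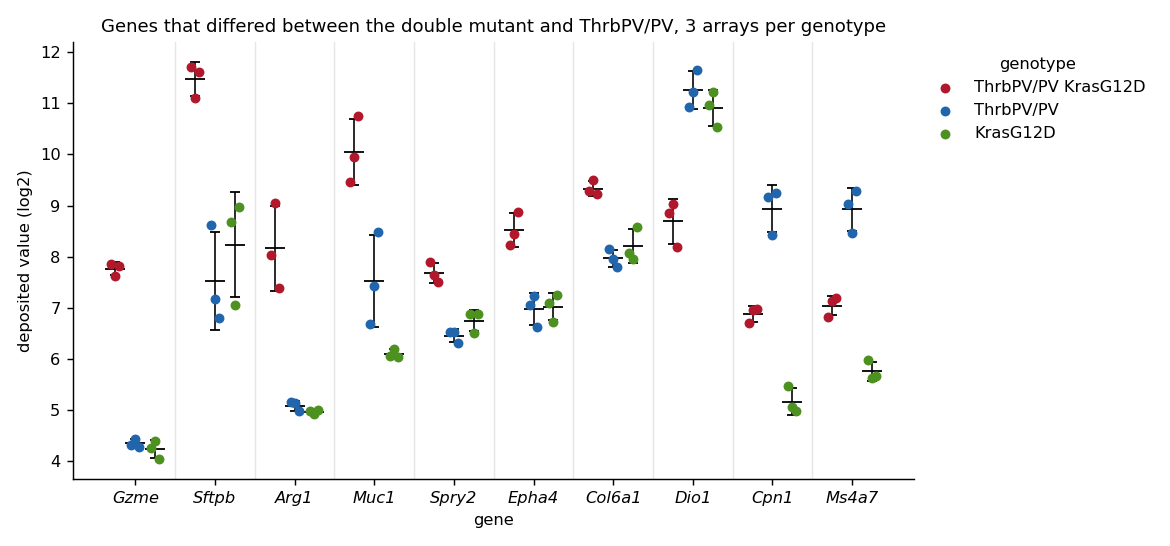
Log2 values of 10 genes on each array, by genotype, with 3 arrays per genotype as points and the mean and SD as bars. Gzme lay at 7.76 on average in the double mutants and at 4.35 and 4.23 in ThrbPV/PV and KrasG12D, and Dio1 at 8.69 against 11.26 and 10.91.

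Of the 24 tested MAPK output genes, 10 passed, all of them higher, and 18 did so adjusted over the list alone. Their median difference was 0.85 (camera adjusted p = 1.42e-11; adjusted p = 0.165 with an estimated correlation). The ephrin receptors Epha4 (1.55) and Epha2 (1.25), the feedback inhibitor Spry2 (1.22) and the transcription factor Etv4 (0.79) were among them. Of the 7 handling stress genes, which include other immediate early genes, Junb (0.61) and Ier2 (0.51) rose, and the smooth muscle and pericyte list had a median of 0.54 with 1 of 8 passing, Cspg4 (1.00).

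Extracellular matrix genes were higher in 5 of 21 cases (11 adjusted over the list alone), with a median of 0.55 (adjusted p = 2.23e-06; adjusted p = 0.489 with an estimated correlation). They included tenascin C (Tnc, 1.87) and the collagen VI chains Col6a1 (1.37), Col6a2 (1.03) and Col6a3 (0.81). In the epithelial adhesion list 2 of 19 passed, both higher, claudin 4 (Cldn4, 0.81) and the tight junction protein Tjp1 (0.46), against 6 higher and 1 lower adjusted over the list alone. Its median was 0.16 (adjusted p = 0.00609; adjusted p = 0.489 with an estimated correlation). Fibroblast markers had a median of -0.05, with 0 of 8 passing by limma and 0 at an unadjusted p under 0.05.

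Of 26 respiratory chain genes 4 fell (8 adjusted over the list alone), Ndufb8 (-1.20), Uqcrq (-0.43), Cox7b (-0.39) and Ndufb5 (-0.39), and the median was -0.18 (adjusted p = 2.23e-06; adjusted p = 0.489 with an estimated correlation). In the interferon list 1 of 15 fell, the guanylate-binding protein Gbp3 (-1.15), with 6 adjusted over the list alone and a median of -0.44 (adjusted p = 0.000251; adjusted p = 0.489 with an estimated correlation). Without double mutant replicate 1 that median was -0.21. The chemokine Cxcl10 had a difference of -2.16 with an adjusted p of 0.0501. Of 19 unfolded protein response genes 2 fell, the chaperone Dnajb9 (-0.96) and the transcription factor Xbp1 (-0.38), with 3 lower and 1 higher adjusted over the list alone and a median of -0.34 (adjusted p = 0.000738; adjusted p = 0.582 with an estimated correlation). Macrophage markers moved the same way, with a median of -0.51 and 1 of 12 passing, the complement gene C1qc (-0.73), against 6 adjusted over the list alone (adjusted p = 0.0186; adjusted p = 0.924 with an estimated correlation). That call was lost without double mutant replicate 1 (adjusted p = 0.0793) or ThrbPV/PV replicate 3 (adjusted p = 0.0538).

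Thyroid differentiation genes had a median of -0.34, with Dio1 lower and the endocytic receptor Lrp2 (0.67) higher among 21, against 4 lower and 1 higher adjusted over the list alone. The list was called at camera adjusted p = 0.0424 (adjusted p = 0.489 with an estimated correlation). The call was lost after quantile normalization (adjusted p = 0.0652), median centring (0.0627) or a filter at the median (0.0945), with the muscle or adipocyte level as a covariate (0.0985 and 0.0719), and without double mutant replicates 1 or 3, ThrbPV/PV replicate 3 or KrasG12D replicates 1 or 2 (adjusted p = 0.0554, 0.0911, 0.129, 0.0504 and 0.0540). The iodide transporter Slc5a5 (-0.59), the TSH receptor Tshr (-0.44), the anion transporter Slc26a7 (-1.18, adjusted p = 0.0528) and the iodotyrosine deiodinase Iyd (-0.41) did not pass. Skeletal muscle markers had a median of 0.61 with 0 of 12 passing by limma and 0 at an unadjusted p under 0.05 (adjusted p = 0.0429; adjusted p = 0.924 with an estimated correlation), a call lost without double mutant replicates 1 or 3, ThrbPV/PV replicates 2 or 3 or KrasG12D replicates 2 or 3 (adjusted p = 0.0793, 0.539, 0.0955, 0.185, 0.0599 and 0.0539). The muscle median was 0.16 without double mutant replicate 3 and 1.01 without replicate 2. The call was also lost with quantile normalization (adjusted p = 0.0730), a floor at the 40th percentile (0.0583), no filter (0.0722), only these 2 groups in the fit (0.0602) or a covariate (0.821 for the muscle level itself and 0.0680 for the adipocyte level).

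No cell cycle gene passed among 42, by limma or at an unadjusted p under 0.05, and the median was 0.07. Of 39 MYC target genes 1 passed, Aimp2 (-0.77), and Myc itself differed by 0.55 (adjusted p = 0.0844). Thyroid hormone induced genes had a median of 0.01, with only Aldh1a3 (1.49) passing of 14. The medians of the cAMP and TSH response (0.29), mesenchymal transition (0.13), glycolysis and hypoxia (0.02), Wnt target (0.03) and p53 target (-0.02) lists did not pass. Within them Slc2a1 (0.47) and the stem cell marker Lgr5 (1.57) rose. Among the markers, the adipocyte (-0.22), endothelial (0.02), C cell and neuroendocrine (-0.07), T cell (-0.20), airway (-0.45), squamous (0.21), peripheral nerve (0.16) and sex linked (-0.02) medians did not pass, though the adipocyte lipase Lpl fell by 1.69. Of 5 cartilage markers Col9a1 rose and Cnmd fell.

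The count of 612 moved with the settings: 1007 with array weights, 327 with only these 2 groups in the fit, 193 with a replicate block, 130 at a 2-fold threshold, and 92 and 126 with the muscle and adipocyte levels as covariates. When 1 array was left out it was 198, 260 and 227 without double mutant replicates 1, 2 and 3, 264, 350 and 70 without ThrbPV/PV replicates 1, 2 and 3, and 285 without KrasG12D replicate 1. Of the 47 named genes that passed, 12 did so in every such fit that tested them: Gzme, Arg1, Epha4, Aldh1a3, Col6a1, Col6a2, Spry2, Aimp2, Ms4a7, Cd5l, Cpn1 and Dio1. Gzme and Arg1 lay above the filter level only on the double mutant arrays. Without any 1 of these arrays they failed the filter and were not tested, so their calls were not checked against the loss of a double mutant array. Sftpb, Cspg4, Etv4, C1qc, Lypd6b and Cd180 were lost only without ThrbPV/PV replicate 3 (adjusted p = 0.0513 to 0.0637). The other 29 were each lost without at least 2 of the arrays in turn (adjusted p up to 0.157). With quantile normalization 54.5% of the calls were higher, against 43.8% here and 36.1% with median centring.

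The double mutants were next compared with KrasG12D, which asks what the mutant receptor adds to activated Kras, and the differences were far wider. Cell cycle genes (35 of 42), macrophage markers (11 of 12), MAPK output (17 of 24) and extracellular matrix genes (14 of 21) were higher in the double mutants, and respiratory chain (25 of 26) and unfolded protein response genes (12 of 19) were lower. With an estimated correlation the calls of these lists were lost (adjusted p = 0.281 to 0.329). Parathyroid, adipocyte and skeletal muscle markers were much higher in KrasG12D. Parathyroid hormone (Pth) lay at 12.38 there and at 3.79 in the double mutants, at least 110-fold lower (adjusted p = 8.02e-11). Airway markers went both ways, with 1 higher (Tekt1, 2.67) and 1 lower (Bpifa1) of 4. So did cartilage markers, with 2 higher and 1 lower of 5, and camera called neither list. In all 4516 genes passed, 2276 higher and 2240 lower, and 659 and 385 of them by at least 2-fold. The groups did not overlap in 47.3% of genes, against 10% by chance.

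The largest rises were in Elobl (5.35), the neuroendocrine vesicle protein Ptprn (4.97), fibrinogen gamma (Fgg, at least 23.3-fold, 5.39 to 10.16), the phosphate transporter Slc34a2 (4.70), the chitinase-like protein Chil1 (4.52), lipocalin 2 (Lcn2, 4.51) and Dapl1 (4.26). Dcpp1 (4.48, adjusted p = 0.0469) was lost without double mutant replicates 1 or 2, ThrbPV/PV replicate 1 or KrasG12D replicates 2 or 3 (adjusted p = 0.0600 to 0.134). Beside Pth, the largest falls were in chromogranin A (Chga, -6.41, from 12.58 to 6.17), the brown fat uncoupling protein Ucp1 (at least 24.6-fold), the airway secretory gene Bpifa1 (at least 15.0-fold), tenomodulin (Tnmd, at least 18.3-fold), klotho (Kl, at least 11.6-fold), the brown fat and muscle gene Cox8b (-4.35) and the calcium-sensing receptor Casr (-4.07), which the parathyroid uses.

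Of 42 cell cycle genes 35 were higher (39 adjusted over the list alone), with a median of 1.11 (adjusted p = 3.27e-13; adjusted p = 0.329 with an estimated correlation). Cyclin B2 (Ccnb2, 2.21), Racgap1 (1.85), the mitotic kinesin Kif11 (1.49) and the checkpoint kinase Bub1b (1.47) stood for them. Macrophage markers moved with them: 11 of 12 were higher, also adjusted over the list alone, and the median was 1.58 (adjusted p = 6.14e-07; adjusted p = 0.296 with an estimated correlation), with lysozyme 2 (Lyz2, 1.97), C1qa (1.71) and C1qc (1.55). MAPK output genes were higher in 17 of 24 cases (18 adjusted over the list alone), with Plaur (1.80), Epha2 (1.66), Ier3 (1.15) and Lif (0.83), and a median of 0.99 (adjusted p = 3.78e-07; adjusted p = 0.281 with an estimated correlation).

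Extracellular matrix genes were higher in 14 of 21 cases (15 adjusted over the list alone), led by the protease inhibitor Timp1 (4.07), Thbs2 (2.30), periostin (Postn, 1.83) and Mmp14 (1.61), at a median of 0.66 (adjusted p = 6.37e-07; adjusted p = 0.281 with an estimated correlation), or 1.07 without KrasG12D replicate 3. In the mesenchymal transition list 10 of 18 were higher, with Tgfbi (3.41), Tgfb1 (1.33), S100a4 (1.08) and vimentin (Vim, 0.74), against 11 higher and 1 lower adjusted over the list alone (median 0.46, adjusted p = 0.000189; adjusted p = 0.281 with an estimated correlation). The cAMP and TSH response list had 5 of 11 higher on both counts, adjusted over all genes and adjusted over the list alone, among them the phosphodiesterases Pde4d (1.93), Pde10a (1.22) and Pde4b (1.16), with a median of 0.77 (adjusted p = 0.00172; adjusted p = 0.281 with an estimated correlation). Handling stress genes were higher in 5 of 7 cases and lower in 1, with Atf3 at 1.67 (median 0.94, adjusted p = 0.0168; adjusted p = 0.596 with an estimated correlation), a call lost with a filter at the median (adjusted p = 0.0731) or the muscle level as a covariate (0.0658).

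Of 26 respiratory chain genes 25 fell, on both adjustments, with a median of -0.47 (adjusted p = 1.03e-09; adjusted p = 0.281 with an estimated correlation), among them Sdhc (-0.82), Uqcrq (-0.74), Ndufb5 (-0.56) and Cox7b (-0.55). Of 19 unfolded protein response genes 12 fell and 1 rose (14 and 1 adjusted over the list alone), with Derl3 (-3.23), Herpud1 (-1.65), Dnajb9 (-1.51) and Xbp1 (-0.72), and a median of -0.72 (adjusted p = 1.00e-05; adjusted p = 0.329 with an estimated correlation). Muscle and fat markers were lower here too, and whether they account for the fall of the respiratory chain genes stays open. Skeletal muscle markers fell in 10 of 12 cases (median -2.01, adjusted p = 3.03e-05; adjusted p = 0.596 with an estimated correlation), with myosin heavy chain Myh4 at least 8.21-fold lower, and adipocyte markers in 7 of 7 (median -3.14, adjusted p = 3.03e-05; adjusted p = 0.356 with an estimated correlation). C cell and neuroendocrine markers fell in 5 of 6 cases and rose in 1 (median -2.28, adjusted p = 0.000132; adjusted p = 0.296 with an estimated correlation), a call lost without any of the 3 KrasG12D arrays. The median was then -0.84, -0.72 and -0.93 without replicates 1, 2 and 3 (adjusted p = 0.0705, 0.0834 and 0.0874), since Chgb, Scg2 and Pcsk1, bright only in KrasG12D, then failed the filter and were not tested. In these 3 marker lists the counts adjusted over the list alone were the same. The C cell and neuroendocrine list joins both kinds of marker, so its fall does not show a change in C cells.

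Thyroid differentiation genes went both ways, 6 higher and 4 lower of 21 on both adjustments, with a median of 0.01. Lrp2 (1.09), the transcription factor Hhex (0.75) and Nkx2-1 (0.52) rose, and Dio1 (-2.22) and Slc26a7 (-1.52) fell. Slc5a5 (1.29, adjusted p = 0.0871), Tshr (0.99, adjusted p = 0.0849) and Foxe1 (0.01) did not pass. Thrb fell by 0.59 and Myc rose by 0.61 (adjusted p = 0.0192). These calls were lost without KrasG12D replicate 2 (adjusted p = 0.0703 for Nkx2-1, 0.0922 for Thrb and 0.0568 for Myc). That of Nkx2-1 was also lost without double mutant replicates 1 or 2 or KrasG12D replicate 1 (adjusted p up to 0.0863), that of Thrb without double mutant replicates 2 or 3 or KrasG12D replicate 1 (up to 0.0900), and that of Myc without double mutant replicate 3 (0.0619). Of 118 named genes that passed, 102 did so in every fit without 1 array that tested them.

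Other lists did not pass by camera. By fry, p53 targets (adjusted p = 0.00796) and epithelial adhesion (0.0230) were called higher. It called thyroid hormone induced genes (0.00303) and peripheral nerve markers (0.0312) lower. MYC targets had 2 higher and 8 lower of 39 (1 and 5 adjusted over the list alone), with Npm1 (0.48) higher and Tmem97 (-0.81) lower. Thyroid hormone induced genes had 2 higher and 4 lower of 14, on both adjustments, with the lipogenic gene Thrsp (-3.98) and Bcl3 (0.75). Epithelial adhesion had 8 higher and 1 lower of 19, with keratin 19 (Krt19, 1.13). The interferon list had 0 higher and 3 lower of 15 by limma, with Rsad2 (-0.90), glycolysis and hypoxia 1 higher and 2 lower of 18, with Ndrg1 (1.51), and the p53 list 4 higher and 1 lower of 13, with Eda2r (1.12). Among Wnt targets Lgr5 rose at least 7.06-fold and Rnf43 fell by 0.50. The B cell gene Cd79b (-1.23) and the mast cell gene Kit (-1.73) fell, and the erythroid gene Alas2 (-0.92) did not pass.

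The mean level of the skeletal muscle markers was 82.5% explained by genotype, and that of the adipocyte markers 90.9%. With the muscle level as a covariate, chosen after the data had been seen, 1124 genes passed, and with the adipocyte level 25. With the adipocyte level the respiratory chain median was -0.07 (adjusted p = 0.848) and the MAPK output median 0.34 (adjusted p = 0.102). The differences of Nkx2-1, Myc and Thrb turned, and none of them then passed (limma adjusted p = 0.811, 0.929 and 0.936). With the muscle level, which is built from the muscle markers, that list had a median of -0.10 (adjusted p = 0.918).

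**Figure D2:**
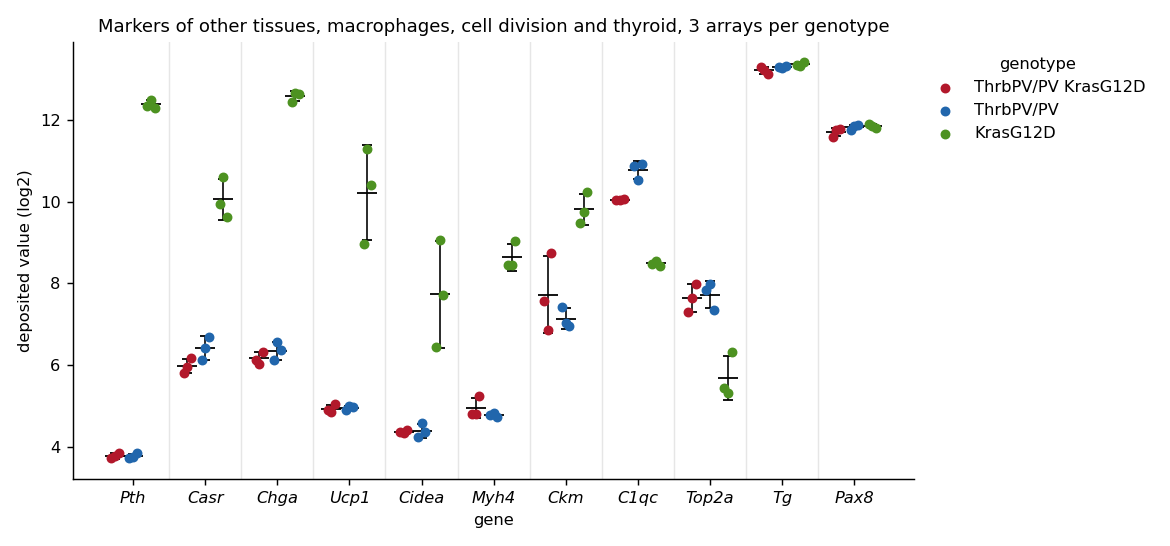
Log2 values of 11 genes on each array, by genotype, with 3 arrays per genotype as points and the mean and SD as bars. Pth, Casr, Chga, Ucp1, Cidea, Myh4 and Ckm were highest on the 3 KrasG12D arrays, C1qc and Top2a lowest on them, and Tg was the highest value of each array.

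ThrbPV/PV was compared with KrasG12D to set the 2 mutations side by side. Cell cycle genes (32 of 42) and macrophage markers (11 of 12) were higher in ThrbPV/PV, and the calls of these lists were lost with an estimated correlation (adjusted p = 0.396 and 0.234). The iodide transporter Slc5a5 (1.87) and Tshr (1.43), the receptor that TSH signals through, were higher too, with calls that were lost without some of the arrays. MAPK output genes hardly parted the groups, with a median of 0.13. The largest fall was again that of Pth, at 3.78 against 12.38, at least 112-fold lower (adjusted p = 7.99e-11). In all 3164 genes passed, 1816 higher and 1348 lower, and 610 and 260 of them by at least 2-fold. The groups did not overlap in 44.1% of genes, against 10% by chance.

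The largest rises were in Elobl (5.64), Lcn2 (4.88), Dapl1 (4.69), Slc34a2 (4.44), Tmem35a (4.42), Timp1 (3.96), the lipase Lipk (3.94) and the chemokine Ccl3 (3.91). Beside Pth, the largest falls were in Chga (-6.22), Ucp1 (at least 25.1-fold), Cox8b (-4.73), Kl (at least 11.9-fold), the fast muscle myosin light chain Myl1 (-4.42), Tnmd (-4.12) and the muscle calcium pump Atp2a1 (-3.88). The call of Myl1 (adjusted p = 0.0291) was lost without ThrbPV/PV replicates 2 or 3 or any KrasG12D array (up to 0.0911), and 78 of 98 named genes that passed did so in every such fit that tested them.

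Of 42 cell cycle genes 32 were higher (36 adjusted over the list alone), with a median of 1.03 (adjusted p = 3.27e-14; adjusted p = 0.396 with an estimated correlation), among them Ccnb2 (2.04), topoisomerase Top2a (2.03), Kif11 (1.48) and Kif20a (1.46). Macrophage markers were higher in 11 of 12 cases, with 11 higher and 1 lower adjusted over the list alone. Cd68 (2.88), C1qc (2.29), C1qa (2.21) and C1qb (2.03) led them, and the median was 2.10 (adjusted p = 1.47e-09; adjusted p = 0.234 with an estimated correlation). In the MAPK output list 4 of 24 were higher and 1 lower, on both adjustments, with Plaur (0.99) higher and the ETS factor Etv5 (-1.59) lower. The call of Etv5 was lost without ThrbPV/PV replicate 3 or KrasG12D replicates 1 or 3 (adjusted p up to 0.0707).

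Thyroid differentiation genes were higher in 5 of 21 cases (6 adjusted over the list alone), with the anion exchanger Slc26a4 at least 1.90-fold higher and Hhex at 0.59, and a median of 0.35 (adjusted p = 0.0204; adjusted p = 0.384 with an estimated correlation). That call was lost without ThrbPV/PV replicate 3 (median 0.23, adjusted p = 0.0521), without genes that hold identical values (0.0841) and with the muscle or adipocyte level as a covariate (0.925 and 0.222). The call of Slc5a5 (adjusted p = 0.0314) was lost without ThrbPV/PV replicates 1 or 3 or KrasG12D replicates 1 or 3 (up to 0.104), and that of Tshr (adjusted p = 0.0316) without double mutant replicate 3, any ThrbPV/PV array or KrasG12D replicate 1 (up to 0.0807). On 1 ThrbPV/PV array Slc5a5 lay under the highest KrasG12D array (10.65 against 10.69). The cAMP and TSH response list had 4 of 11 higher (5 adjusted over the list alone), with Pde4d (1.66) and Pde4b (1.25), and a median of 0.56 (adjusted p = 0.00448; adjusted p = 0.384 with an estimated correlation). It was lost without genes that hold identical values (adjusted p = 0.0527) and with the muscle level as a covariate (0.0552). Thyroid hormone induced genes fell in 3 of 14 cases on both adjustments, Thrsp (-3.47), Ucp3 (at least 1.63-fold) and Aldh1a3 (-0.85), at a median of -0.24 (adjusted p = 0.0145; adjusted p = 0.384 with an estimated correlation), and without KrasG12D replicate 2 the list had an adjusted p of 0.0866. Thrsp is a gene of fat and Ucp3 of muscle, whose markers fell with them (medians -2.70 and -2.66). With the adipocyte level as a covariate the list's median was -0.17 (adjusted p = 0.947). Genotype explained 90.9% of that level, and with it 47 genes passed in this comparison against 3164 without. The lost call therefore does not tell whether fat gave the fall of the list.

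The mesenchymal transition list had 8 higher and 1 lower of 18 on both adjustments, with Tgfbi (3.23) and Tgfb1 (1.01), and a median of 0.50 (adjusted p = 0.00120; adjusted p = 0.384 with an estimated correlation). The extracellular matrix list had 8 higher and 2 lower of 21 on both adjustments, with Postn (1.81) and Lox (1.72) higher and Tnc (-2.15) lower (median 0.22, adjusted p = 0.0366; adjusted p = 0.683 with an estimated correlation), and its call was lost without ThrbPV/PV replicate 1 or KrasG12D replicates 1 or 2 (adjusted p = 0.0954, 0.107 and 0.154). Its median was 0.13 without KrasG12D replicate 1 and 0.35 without replicate 3. The call was also lost with a filter at the median (adjusted p = 0.0628), without genes that hold identical values (0.0808) and with the adipocyte level as a covariate (median -0.13, adjusted p = 0.918). Respiratory chain genes fell in 8 of 26 cases (13 lower and 1 higher adjusted over the list alone), with Sdha (-0.58), Uqcrc1 (-0.49) and Sdhc (-0.48), at a median of -0.25 (adjusted p = 0.000145; adjusted p = 0.563 with an estimated correlation). Unfolded protein response genes fell in 3 of 19 cases (6 adjusted over the list alone), Herpud1 (-1.32), Dnajb11 (-0.87) and Xbp1 (-0.34), at a median of -0.35 (adjusted p = 0.00314; adjusted p = 0.585 with an estimated correlation). That median was -0.56 without KrasG12D replicate 3, and the call was lost with the adipocyte level as a covariate (adjusted p = 0.270). The calls of Dnajb11 and Xbp1 were lost without ThrbPV/PV replicates 1 or 2 or KrasG12D replicate 1, that of Dnajb11 also without KrasG12D replicate 2 (adjusted p up to 0.104 and 0.0663).

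Skeletal muscle markers fell in 11 of 12 cases (12 adjusted over the list alone), with Myh4 at least 8.41-fold and Tnnt3 (-2.94) (median -2.66, adjusted p = 4.28e-08; adjusted p = 0.365 with an estimated correlation), a call lost with the muscle level itself as a covariate (adjusted p = 0.777). Adipocyte markers fell in 6 of 7, with Cidec (-2.70) and Plin1 (-2.36) (median -2.70, adjusted p = 4.99e-05; adjusted p = 0.365 with an estimated correlation), and C cell and neuroendocrine markers in 5 of 6 with 1 higher (median -2.39, adjusted p = 4.99e-05; adjusted p = 0.234 with an estimated correlation), each the same adjusted over the list alone. The last call was lost without KrasG12D replicates 1, 2 or 3, with medians of -0.74, -0.62 and -0.82 (adjusted p = 0.0677, 0.0860 and 0.0748), again with Chgb, Scg2 and Pcsk1 not tested. Here too that list does not tell C cells from other neuroendocrine cells. Handling stress genes were higher in 3 of 7 cases on both adjustments, Atf3 (1.98) among them (median 0.37, adjusted p = 0.0392; adjusted p = 0.518 with an estimated correlation), and were lost without ThrbPV/PV replicates 1 or 2 or KrasG12D replicates 1 or 3 (adjusted p = 0.0667 to 0.0784), with a filter at the median (0.102), without genes that hold identical values (0.0661) and with the muscle or adipocyte level as a covariate (0.261 and 0.176). The interferon list had 4 higher and 1 lower of 15 (6 and 1 adjusted over the list alone) with a median of 0.43 and did not pass, although Cxcl10 (2.25), Gbp3 (1.35) and Oas1a (0.79) rose.

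The MYC target, epithelial adhesion, glycolysis and hypoxia, Wnt target and p53 target lists did not pass by camera, with medians of -0.02, 0.04, -0.11, -0.10 and 0.13. By fry the p53 targets were called higher (adjusted p = 0.00313). Also by fry, squamous (0.0189) and peripheral nerve (0.00812) markers were called lower, which camera did not call. Nkx2-1 (0.23), Myc (0.05), Foxe1 (-0.002) and Thrb (-0.16) did not pass. Among other markers, the neutrophil gene Csf3r (0.91) rose, Cd79b (-1.02) fell, and the mast cell gene Kit (-0.95) did not pass. With quantile normalization 47.7% of the calls were higher, against 57.4% here. The count was 112 with the skeletal muscle level and 47 with the adipocyte level as a covariate. With the adipocyte level the respiratory chain median turned to 0.07 and was not called (camera adjusted p = 0.270).

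**Figure D3:**
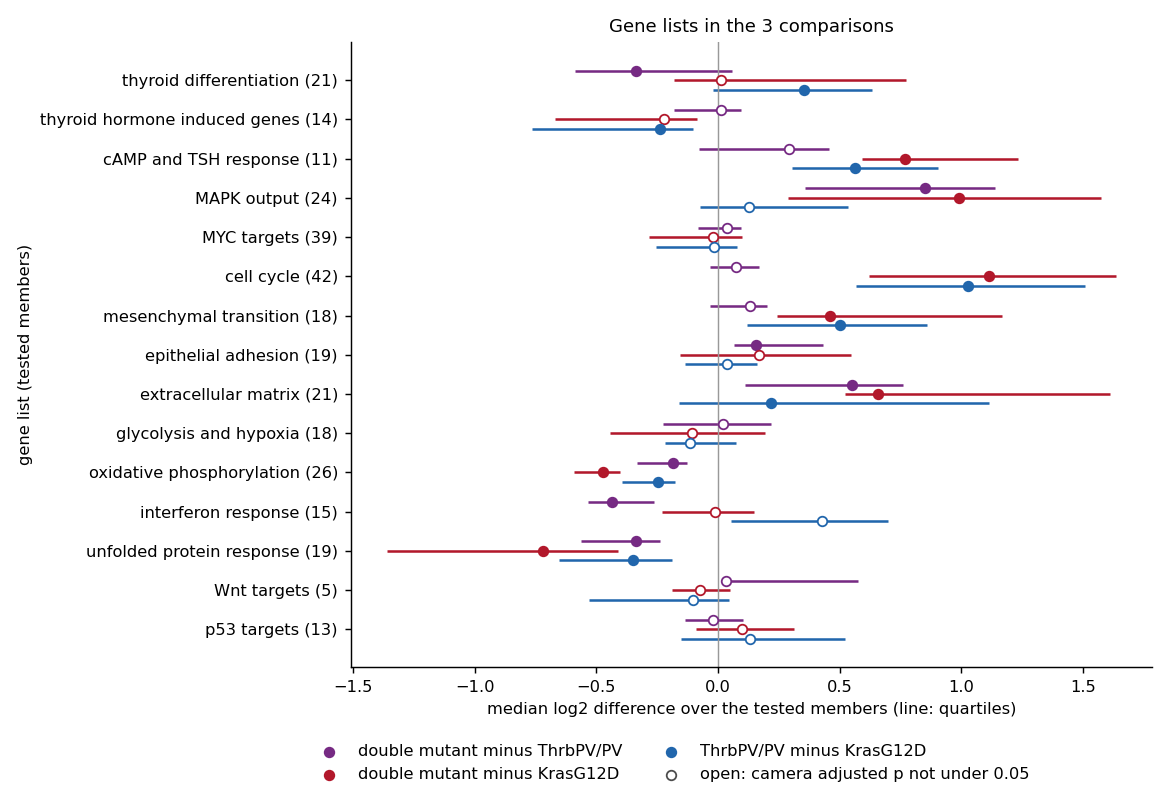
Median log2 difference of each program list in the 3 comparisons, with lines from the lower to the upper quartile and filled points for lists called by camera at its preset correlation. MAPK output medians were 0.85 and 0.99 in the double mutants against ThrbPV/PV and KrasG12D and 0.13 between the single mutants, and cell cycle medians were 0.07, 1.11 and 1.03.

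Genes that changed the same way in the double mutants against both single mutants numbered 407, 214 higher and 193 lower, and 40 changed in opposite ways, 38 of them lower than in ThrbPV/PV and higher than in KrasG12D. Gzme, Sftpb, Arg1, Muc1, Krt20 and the GABA receptor subunit Gabrp (2.24 and 2.47) led the rises. Cnmd, Dio1, the lipid enzymes Dgat2 (-1.79 and -2.77) and Lpl (-1.69 and -2.46), Slc38a3 and Lypd6b (-1.64 and -1.73) led the falls. Independent lists of these sizes would share 46.3 and 58.5. In 50 simulations of unchanged groups with the double mutant arrays shared, 0.02 calls were shared on average, but unchanged groups give hardly any calls to share, so this figure decides nothing. The fold changes of both comparisons had a covariance of 0.0763 against 0.0124 in the simulations, and their correlation (r = 0.376) lay under that of the simulations (r = 0.501). Sharing a group gives unchanged comparisons that r by design, so the lower observed r does not mean less overlap than by chance. The simulated covariance is what the spread of the shared arrays within their group would give, so that spread makes up only part of the observed covariance. The 3 shared arrays are too few to split, so their part in the number of shared genes stays open. The overlap was 658 with array weights, 216 with only the 2 groups compared in each fit, 140 with a replicate block, 71 at a 2-fold threshold, and 48 and 2 with the muscle and adipocyte levels as covariates. It was 145, 191 and 170 without double mutant replicates 1, 2 and 3, 190, 192 and 55 without ThrbPV/PV replicates 1, 2 and 3, and 195 without KrasG12D replicate 1.

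Against KrasG12D, the double mutants and ThrbPV/PV had 1318 higher and 1062 lower genes in common, where independent lists would share 314 and 229. The simulations shared 0 on average, which again decides nothing. Elobl, Lcn2, Slc34a2, Dapl1 and Timp1 were among the shared rises and Pth, Chga, Ucp1, Cox8b and Kl among the shared falls. The covariance was 0.307 (r = 0.853) against 0.0124 (r = 0.501) in the simulations, and the 3 shared KrasG12D arrays likewise are too few to split.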

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

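All tests of explanations in this part were chosen only after the result was seen. Probe sets outside the named genes also carried signal: of 1972 that had no symbol or several and passed the same filter, 36 passed limma's test in the double mutants against ThrbPV/PV (10 higher, 26 lower), 332 in the double mutants against KrasG12D (157 and 175) and 258 in ThrbPV/PV against KrasG12D (136 and 122). They were singled out because the comparisons above use only probe sets with 1 symbol, and which genes they read is not known here. Groups of 3 arrays are too small for the test of single samples far from the others, so none was made.

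Parathyroid, adipocyte and skeletal muscle markers were higher in KrasG12D than in both other groups. Of 21 tested markers 18, or 85.7%, were higher on every KrasG12D array than on every other array, against 14.1% of all genes and 1.19% by chance. Pth, Casr, Ucp1, Cidea and Myh4 belong to tissue that lies beside the thyroid, and such tissue in the KrasG12D samples may be the source. This share restates the pattern, so it decides nothing about its source, which stays open. A single mislabelled array is argued against, since the lowest KrasG12D array lay 8.44 above the highest other array in Pth. Whether the tissue was taken along at dissection, or whether a larger thyroid in the other genotypes held a smaller share of it, was not tested. The airway and cartilage lists did not share the pattern. Their medians against KrasG12D were 0.16 and -0.01 in the double mutants and -0.08 and -0.09 in ThrbPV/PV, and camera called none of them.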

How the results depend on the processing

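The counts of changed genes were 612 in the double mutants against ThrbPV/PV, 4516 in the double mutants against KrasG12D and 3164 in ThrbPV/PV against KrasG12D. Over 3 groups 4577 genes differed, and the overlap was 407. These counts stayed within 1.5 times in 83 of 118 pairs of a count and an alternative. Outside the fits without 1 array, those within ranged from 486 to 690, 3772 to 4964, 2498 to 4177, 3454 to 5429 and 326 to 479. Where counts moved, the cause was not tested unless said. Array weights gave 1007 and an overlap of 658, only the 2 groups compared gave 327 and 216 from fewer arrays, and the replicate block gave 193 and 140. Arrays with the same replicate number did not pair (r = -0.27 to 0.04 in 9 pairs, -0.13 to 0.19 in 18 others). A 2-fold threshold, which only removes genes, left 130, 1044, 870 and an overlap of 71. The muscle level as a covariate, added like the adipocyte level after the data had been seen, left 92, 1124, 112, 1363 over 3 groups and an overlap of 48, and the adipocyte level 126, 25, 47, 204 and 2. Genotype explained 82.5% and 90.9% of these levels, so the covariates also take up the groups' difference. Without 1 array the counts were 70 to 608, 3186 to 4419, 2131 to 3316, 2975 to 4115 and 55 to 414. Of 34 list calls all were lost with an estimated correlation, and 23 were kept under every other alternative but the covariates. Over all lists 4 reversed, 28 were gained, 93 lost and 1946 kept their side and direction; for named genes these were 25, 118, 806 and 8878. A further 113 uncalled values of named genes changed sign and stayed uncalled. With the muscle level, the interferon response turned to 0.533 in the double mutants against KrasG12D and was then called by camera (adjusted p = 0.0255). Zmat3 turned to -0.162, Rsad2 to 0.103, Des to 0.204 and Myl1 to 2.806 in ThrbPV/PV against KrasG12D, and none of these genes then passed (limma adjusted p = 0.0911 to 0.922). With the adipocyte level, in the double mutants against KrasG12D, the adipocyte list turned to 0.247, Dcpp1 to -1.966, Sftpb to -0.444, Cldn4 to -0.486, Erbb3 to -0.531, Trp53inp1 to -0.06, Myc to -0.187, Nkx2-1 to -0.368, Npm1 to -0.062, Thrb to 0.191, Ucp3 to 0.882, Plin1 to 0.004, Cidec to 0.247, Cidea to 0.782 and Bpifa1 to 0.72. In ThrbPV/PV against KrasG12D, oxidative phosphorylation turned to 0.074, the adipocyte list to 0.276, Cdh1 to -0.09, Uqcrc1 to 0.062, Ucp3 to 0.557, Cidec to 0.302, Cidea to 0.128 and Bpifa1 to 1.009. None of the values that turned with the adipocyte level passed (adjusted p = 0.268 to 0.998 by limma for genes and camera for lists). They are lost calls and not calls in the other direction. Plin1, Cidec and Cidea are among the markers that make up this level, so it removes their difference and that of the adipocyte list by design. Scgb3a1 ranged there from -0.503, without ThrbPV/PV replicate 2, to 0.325 when 1 array was left out. The value of -0.503 passed limma's test (adjusted p = 0.0102), while the main fit gave 0.008 (adjusted p = 0.992). Offsets before log2 were not run, since the values are log2, nor was leaving out probe sets that read several transcripts, since their names do not mark them. Scaling moved the median of all genes by at most 0.1. Genes near the 40th percentile of an array are where signal over background limits the values.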

Other observations

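The symbol families and the explanations tested here were chosen only after the result was seen; the counts over other splits of the arrays were planned. Among 216 families of genes that share a symbol prefix and have at least 8 tested members, camera called 14 in the double mutants against KrasG12D, 6 higher and 8 lower, 13 in the double mutants against ThrbPV/PV and 6 in ThrbPV/PV against KrasG12D. With an estimated correlation 0 were called in any comparison (lowest adjusted p = 0.636), so no theme is drawn from them, and 6 of the 14 are given as examples. In the double mutants against KrasG12D 34.3% of all tested genes passed, adipocyte and skeletal muscle markers lay lower (medians -3.14 and -2.01) and macrophage markers higher (1.58). With the adipocyte level as a covariate the oxidative phosphorylation list had a median of -0.075 (adjusted p = 0.848). Of 9 Ndufb subunits of complex I, 8 fell and 0 rose by limma (median -0.56, camera adjusted p = 0.0067; adjusted p = 0.647 with an estimated correlation), and 10 of 14 Ndufa subunits fell (median -0.43, adjusted p = 0.0067; adjusted p = 0.706 with an estimated correlation). Of 11 Coq genes, which make ubiquinone, 8 fell and 1 rose (median -0.48, adjusted p = 0.0210; adjusted p = 0.659 with an estimated correlation). Matrix metalloproteinases (Mmp) rose in 7 of 13 cases and fell in 1 (median 0.54, adjusted p = 0.0185; adjusted p = 0.636 with an estimated correlation). Integrin alpha chains (Itga) rose in 7 of 12 cases (median 0.62, adjusted p = 0.0185; adjusted p = 0.636 with an estimated correlation) and integrin beta chains (Itgb) in 6 of 10 (median 0.58, adjusted p = 0.0225; adjusted p = 0.636 with an estimated correlation).

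Cell cycle genes were higher than in KrasG12D in ThrbPV/PV (32 of 42, median 1.03; adjusted p = 0.396 with an estimated correlation) and in the double mutants (35 of 42, median 1.11; adjusted p = 0.329 with an estimated correlation). A lower share of thyroid cells in the KrasG12D samples would lower cell cycle and thyroid genes alike, and was weighed by 95% intervals from a bootstrap over genes and from the spread of list means over arrays. In ThrbPV/PV the cell cycle median exceeded the thyroid median by 0.67 (0.23 to 1.15 over genes), but the means differed by 0.63 (-0.16 to 1.43 over arrays), so that cause stays open there. In the double mutants the excess was 1.10 (0.21 to 1.48) and 1.07 (0.27 to 1.87 over arrays). That would argue against it as the whole cause if thyroid genes followed only the share of thyroid cells. But they went both ways there (6 higher and 4 lower of 21), and their median against ThrbPV/PV was -0.34. A fall of thyroid genes in the double mutants could give the excess, so that cause stays open there too. Macrophages as the only source stay open: in the double mutants against ThrbPV/PV the macrophage mean was lower (-0.36, -0.70 to -0.02 over arrays) and the cell cycle median was not (0.07, -0.01 to 0.13 over genes), which speaks against them, but the cell cycle mean over arrays (0.07, -0.52 to 0.66) leaves room for a fall.

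MAPK output genes were higher in the double mutants than in ThrbPV/PV in 10 of 24 cases (median 0.85). The adjusted p was 0.165 by camera with an estimated correlation and 0.00425 by fry. Activated Kras could raise them, but KrasG12D alone did not lie above ThrbPV/PV (median 0.13 in ThrbPV/PV against KrasG12D). The double mutants lay above KrasG12D too (median 0.99), and parathyroid, adipocyte and skeletal muscle markers were higher on the KrasG12D arrays. Whether activated Kras is the cause therefore stays open. As for handling of the tissue before RNA extraction, the list exceeded the 7 handling stress genes by 0.34 in median (0.04 to 1.20 over genes). In mean the excess was 0.52 (0.06 to 0.99 over arrays), and without 5 immediate early genes the list's median was 0.89. But the 7 genes went both ways, Junb by 0.61 and Hspa1a by -0.26, which lowers their mean. The excess therefore argues only weakly against handling as the whole cause. More skeletal muscle is argued against by a median of 0.85 (0.43 to 0.99) and a mean of 0.74 (0.39 to 1.09 over arrays) with the muscle level as a covariate. More stromal cells stay open: the list exceeded smooth muscle and pericyte markers by 0.31 in median (-0.09 to 0.89) and by 0.35 in mean (-0.05 to 0.76 over arrays), and fibroblast markers by 0.98 in mean (0.21 to 1.76 over arrays). The MAPK list may therefore hold a stromal part of unknown size.

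Of the 10 splits of 6 arrays into 3 and 3, only 1, the real one, gave as many genes in each pair of genotypes. The counts were 612 against at most 1 in the other splits for the double mutants and ThrbPV/PV, 4516 against 0 for the double mutants and KrasG12D, and 3164 against 0 for ThrbPV/PV and KrasG12D. These splits are too few for a share under 0.05. Over 3 groups, 1 of 100 drawn splits, the real one, gave 4577 genes and the highest other gave 2450. This is the lowest share that 100 splits can give, so chance alone is an unlikely source of the count. The 5 other drawn splits that kept the 3 KrasG12D arrays together gave 2074 to 2450 genes and the rest at most 19, which points to a structure of the samples. Much of the count thus rests on the KrasG12D arrays, and such splits cannot tell genotype from batch or dissection.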
